A study of Macaca fascicularis with 48 samples.

How the data were processed

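Messenger RNA was measured in 48 libraries of 6 tissues from cynomolgus monkeys, with 4 control and 4 treated libraries per tissue. Per the labels, tissue was kept in RNAlater, RNA was extracted with miRNeasy, and stranded libraries were read as 50 bp pairs on a HiSeq 2500. The deposited values are raw counts per gene name, made by the authors with featureCounts 1.4.6-p1 per the file headers, on Ensembl release 94 of the Macaca_fascicularis 5.0 build, after alignment with STAR 2.5.3a per the submitters' processing notes. The command in the file headers sets neither paired counting nor a strand, so each mate counted as 1 read and reads were not assigned to genes by strand. No per-sample column was left out. Of 16842 gene names, 140 lay on more than 1 chromosome and 422 were Rfam entries, which held 0.0558% of all counts. Totals ran from 35453786 to 53480762 counts per library. The file holds 20 autosomes, the X chromosome and the mitochondrial genome. The sex labels were used as given and were not checked, since 0 of 12 listed Y-linked and X inactivation genes carried a name in the file. JUN and SPRR1A, which the naming rule lists, were also not analysed here.

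Samples were grouped by tissue and dose as the labels give them. Animal identifiers in the labels showed that the same 8 animals gave liver and all cord regions, and that the ganglia came from 4 control and 6 treated animals. Replicates are separate animals, 2 male and 2 female per group of 4.

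Each tissue was tested alone in edgeR 4.0.16 (R 4.3.3) with TMM scaling, filterByExpr by group, a robust quasi-likelihood fit and sex as covariate. Cord counts were also summed over the 3 regions of each animal. The 16 ganglion libraries were fitted in limma 3.58.1 voom with sex and region as covariates and animal as a random block (duplicateCorrelation, statmod 1.5.0). Interactions of treatment with region used the same limma model, and the interaction with sex in liver used edgeR. Cord regions were compared in edgeR with animal as fixed block, and ganglion regions in limma with animal as random block. A gene passed at a Benjamini-Hochberg adjusted p under 0.05, and p values are two-sided. Gene levels are TMM-scaled CPM of the fit they belong to, while marker levels of single libraries are CPM of total counts. Sample levels are given as mean ± SD and log2 fold changes as value ± SE. Coordinates are those of the deposited table.

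A set of 56 gene lists was written before the data were examined, and 53 of them were tested, each in the fits where it had at least 5 tested members. Lists were tested with camera at a preset correlation of 0.01 on voom values, adjusted over the lists of a fit, with camera at an estimated correlation and fry as alternatives. Camera asks whether a list differs from the other genes, and fry whether it differs from no change. Camera takes no block, so for the ganglia fitted together the preset test was run on z-scores of the moderated t, and the estimated correlation was taken from values whitened for the animal block. Each list also got a score per animal, the mean log2 CPM of its members with a prior count of 2, compared between groups by an exact permutation test whose smallest two-sided p is 0.0286 for 4 against 4 and 0.00476 for 4 against 6.

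Genes were named by a rule fixed before any value was seen. It takes the 10 largest rises and falls among genes past the threshold with a mean of at least 1 CPM and no overlap between groups, up to 4 members with the smallest p from each list, the 5 smallest p where fewer than 10 genes pass, and a short set of genes per organ. In region comparisons it takes HOX genes past the threshold and the 5 largest changes each way. Some genes that the rule names are not reported here.

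The alternatives were DESeq2 1.42.0 with its own size factors, limma voom, median-ratio size factors in edgeR, no filter on low counts, a minimum mean of 1 CPM, no sex term, the replicate number as a block, 1 fit of all 48 libraries, other ways of treating the animal, control or treated animals alone, and leaving out each replicate or animal in turn. Settings chosen after the data were seen left out libraries with unusual tissue markers or a high mitochondrial share, or took list scores from total counts or DESeq2 size factors in place of TMM. Treatment labels were also moved to other splits of the animals, at most 100 per comparison. In region comparisons the region labels were reassigned instead, within animals in cord and at random over libraries in ganglia. A split by sex leaves no room for a sex term and was fitted without it.

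Pairing by replicate number was checked from the correlation of deviations from group means. In lumbar cord the same-number correlations were 0.92, 0.19, 0.79 and 0.51 (mean 0.60, against -0.10 for other numbers), which met the rule set for this work for pairing by number, although control and treated animals differ. Only 2 of the 4 controls there correlated best with the treated library of their own number. Libraries of a number also share sex, so the correlations do not establish a pairing. Both libraries that lacked cord markers carried number 1 there. The edgeR fits with and without the number as a block each called 0 genes, with 679 and 250 at an unadjusted p under 0.05. The lumbar cord results and splits use the fit without the block, as planned.

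The pipeline was tested on simulated counts with 200 changed genes per comparison, changed 2-fold or 4-fold. Where animals gave more than 1 region, each gene got a random animal effect with an SD of 0.2 on the log2 scale. That SD was not fitted to the real animal correlation (0.718 in ganglia), so the shares recovered there may not hold for the real data. The shares recovered at 2-fold and 4-fold were 57% and 89% in liver (12660 genes run), 16% and 75% in cervical cord (14192), 12% and 74% in thoracic cord (14062), 0% and 0% in lumbar cord (14313), 22% and 89% in summed cord (15036), 8% and 74% in cervical ganglia (14180), 49% and 87% in lumbar ganglia (14315), and 57% and 95% in ganglia with animal as block (14496). For the interactions they were 2% and 40% by cord region (14738), 7% and 73% by ganglion region (14503), and 6% and 53% by sex in liver (12648). For regions they were 53% and 94% for thoracic against cervical cord (14446), 50% and 87% for lumbar against thoracic (14445), 49% and 85% for lumbar against cervical (14447), and 73% and 97% for ganglia (14216). With a simulated shift of -0.80 in 1 list, the median came out at -0.89 for the cholesterol list in summed cord and -0.77 for the cytoskeleton list in ganglia, and camera called 0 of 52 and 0 of 51 other lists. The simulated genes were drawn independently of each other. These 0 calls therefore cannot show how often camera calls a list of correlated genes in the real data.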

Results

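Messenger RNA was sequenced in 48 libraries from cynomolgus monkeys (Macaca fascicularis) dosed by oral gavage for 13 weeks with GS-8873, a compound that the submitters describe as an inhibitor of hepatitis B virus transcripts. Treated animals received 6 mg/kg/day and control animals 0 mg/kg/day. The 6 tissues were liver, cervical, thoracic and lumbar spinal cord, and cervical and lumbar dorsal root ganglia, the clusters of sensory neuron cell bodies beside the cord. Each tissue had 4 control and 4 treated libraries, from 2 males and 2 females per group. The labels name 10 animals: 4 controls that gave every tissue, and 6 treated animals, because the treated ganglia came from partly different animals than the treated livers and cords. The design text counts 4 treated animals. Total counts per library ran from 35453786 to 53480762, with each mate of a read pair counted as 1 read. The deposited table lists 16842 gene names, with coordinates on the Macaca_fascicularis_5.0 build, and levels below are in CPM.

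In treated liver, the genes of the unfolded protein response, which code for chaperones and disulphide isomerases of the endoplasmic reticulum, were lower as a group: 16 of 16 tested members had negative log2 fold changes (median -0.43), and all 4 treated animals lay below all 4 controls in the list score (exact two-sided permutation p = 0.0286, the smallest that 4 against 4 allows). With scores from total counts in place of TMM scaling, 1 of 4 treated animals lay below all controls (exact p = 0.1143). HYOU1, a large chaperone of that compartment, had 103 ± 18.5 CPM (SD, n = 4) in controls and 64.9 ± 16.7 CPM in treated animals, a log2 fold change of -0.67 ± 0.18 (SE). MANF, a secreted stress protein, gave -0.67 ± 0.17, PDIA4 gave -0.43 ± 0.11 and DNAJB9 gave -0.43 ± 0.10, each with an edgeR adjusted p of 0.341 or more. Of the 16 members, 0 passed over all genes and 7 passed lower when adjusted over the list alone. Transcripts of the mitochondrial genome were also lower as a group, with 12 of 13 negative (median -0.50; exact p = 0.0286) and 5 passing lower when adjusted over the list alone. Control replicate 2 stood apart with a score of 12.93, against 12.25 to 12.36 in the other 3 controls, and a mitochondrial share of 11.83%, against 7.901% to 8.221%, and without it the median was -0.2584. ND5, a subunit of respiratory complex I, went from 6810.0 ± 1263 to 2902 ± 1210.0 CPM and ND3 had a log2 fold change of -0.73 ± 0.15.

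CYP1A1, the cytochrome P450 induced through the aryl hydrocarbon receptor (AHR; chromosome 7, 52757974 to 52764822), stood at 73.8 ± 28.3 CPM in control liver and 214 ± 82.9 CPM in treated liver (SD, n = 4), a log2 fold change of 1.54 ± 0.27 with an edgeR adjusted p of 0.231. All 5 tested AHR target genes had positive values (median 0.58; exact p = 0.0571), among them TIPARP (0.27 ± 0.12) and NQO1 (0.52 ± 0.38), and 1 passed higher when adjusted over the list alone. The gene nearest to the threshold was CENPP, which codes for a centromere protein (chromosome 15, 106499436 to 106787079). It went from 0.906 ± 0.212 to 3.36 ± 0.557 CPM, a log2 fold change of 1.91 ± 0.19 with an edgeR adjusted p of 0.101. It was followed by GNPTG, a subunit of the enzyme that tags lysosomal enzymes (-0.78 ± 0.10), TMPRSS6, a hepatic protease of iron regulation (-0.72 ± 0.10), MIR675 (-0.84 ± 0.12) and LANCL1 (-0.80 ± 0.12), each at an edgeR adjusted p of 0.231. ALB, the gene of serum albumin, gave -0.48 ± 0.12, and SDS, a periportal amino acid enzyme, gave -0.85 ± 0.22. Of the periportal hepatocyte markers, 9 of 9 were negative (median -0.19), and of the T, B and NK cell markers 16 of 20 were positive (median 0.37).

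The genes of the poly(A) polymerases TENT4A and TENT4B and of their partner ZCCHC14, which act on hepatitis B virus transcripts, had log2 fold changes of 0.04 ± 0.15, -0.07 ± 0.13 and 0.01 ± 0.09 in liver. Their levels in treated animals were 10.2 ± 1.397, 16.6 ± 1.86 and 38.4 ± 2.35 CPM (SD, n = 4). CYP3A4, CYP2B6 and CYP7A1 gave 0.21 ± 0.15, -0.45 ± 0.56 and -0.18 ± 0.47. The targets of the xenobiotic receptors CAR and PXR split 6 positive to 8 negative (median -0.06), the cholesterol biosynthesis genes 14 to 10 (median 0.03), and the bile acid genes 7 to 9 (median -0.06).

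Of 12609 genes tested in liver, edgeR called 0 at an adjusted p under 0.05, with 1049 at an unadjusted p under 0.05 against 630 that chance would give. DESeq2 called 193 (43 higher and 150 lower), limma voom called 0, and edgeR with all 48 libraries in 1 fit called 23. In 648 genes (5.14%) the groups did not overlap, against 2.86% expected by chance for 4 against 4. Camera with a preset correlation called the unfolded protein response list at an adjusted p of 3.9e-10, the mitochondrial genome at 1.6e-06 and the AHR targets at 0.0105. With an estimated correlation these became adjusted p = 0.489, 0.694 and 0.489, and by fry 0.245, 0.366 and 0.267. The AHR call rested on treated replicate 3, without which the median was 0.45 and the camera adjusted p 0.0556. Whether liver responses differed by sex was tested with an interaction term in edgeR over 2 animals per sex and group: 0 of 12609 genes passed, with 3.20% of genes at an unadjusted p under 0.05 and 27 calls by DESeq2.

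In treated spinal cord, the genes of cholesterol biosynthesis were lower as a group in every region. Of 24 tested members, 20 were negative in cervical cord (median log2 fold change -0.81), 22 in thoracic cord (-0.90) and 20 in lumbar cord (-0.76). All 4 treated animals lay below all 4 controls in the list score of each region, with an exact two-sided permutation p of 0.0286. Adjusted over the list alone, 15, 16 and 15 members passed lower, and over all genes 0 passed in any region.

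In cervical cord, HMGCS1, which codes for the synthase at the start of the mevalonate pathway (chromosome 6, 43908492 to 43931552), went from 391 ± 83.0 to 112 ± 20.8 CPM (SD, n = 4), a log2 fold change of -1.80 ± 0.17. CYP51A1, the sterol demethylase (chromosome 3, 119841973 to 119863162), went from 174 ± 28.5 to 70.2 ± 7.62 CPM (-1.31 ± 0.12). Both had an edgeR adjusted p of 0.0543. Among the next genes by p were SC5D (-1.14 ± 0.13), a further sterol enzyme, and FADS1 (-1.24 ± 0.16), a fatty acid desaturase. Endothelial and pericyte markers were negative in 12 of 14 (median -0.60; exact p = 0.0286, or 0.05714 with scores from total counts). Motor neuron and cholinergic markers were positive in 8 of 8 (median 1.61) without separating the groups (exact p = 0.143). Of 14235 genes tested, edgeR called 0, with 1356 at an unadjusted p under 0.05 against 712 by chance, and the groups did not overlap in 6.07% of genes. DESeq2 called 108 (40 higher and 68 lower), limma voom 0, edgeR without a filter on low counts 2, and the fit of all 48 libraries 11.

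In thoracic cord, the 5 genes with the smallest p were all lower in treated animals. MSMO1, a sterol oxidase (chromosome 5, 164617710 to 164637030), went from 614 ± 59.9 to 239 ± 29.4 CPM (SD, n = 4), a log2 fold change of -1.37 ± 0.17. IDI1, LSS and DHCR7, of the same pathway, gave -1.26 ± 0.16, -1.30 ± 0.18 and -1.17 ± 0.16, and CYB5R3, an electron donor to sterol and fatty acid enzymes, gave -1.21 ± 0.15, each with an edgeR adjusted p of 0.182 to 0.196. Of the neuronal cytoskeleton genes, 22 of 26 were negative (median -0.42), among them the motor protein gene KIF5C (-0.93 ± 0.21), with 3 of 4 treated animals below all controls (exact p = 0.171). Of 14032 genes tested, edgeR called 0, with 327 at an unadjusted p under 0.05 against 702 by chance (790.0 with the replicate number as a block, and 502 without the 3 libraries with a mitochondrial share over 30%), and the groups did not overlap in 2.02% of genes. DESeq2 called 28, all lower, limma voom 0 and the fit of all 48 libraries 18, all lower.

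In lumbar cord, HMGCS1 went from 209.7 ± 12.9 to 85.3 ± 32.4 CPM (SD, n = 4), a log2 fold change of -1.32 ± 0.31. STARD4, a sterol carrier, and SQLE, the epoxidase of squalene, gave -1.003 ± 0.20 and -0.89 ± 0.19. TREM2, a receptor of microglia, gave 1.12 ± 0.28, and the acute phase gene SERPINA3 3.65 ± 0.87. WIF1 (-2.30 ± 0.35), SLIT3 (-1.001 ± 0.22) and the chemokine gene CXCL9 (-6.18 ± 1.31) were among the 5 smallest p. Control replicate 1 and treated replicate 1 held at most 0.258 CPM of MOG, a gene of central myelin, against at least 330.0 CPM in the other 22 cord libraries. Control replicate 1 also held 19.26 CPM of CXCL9, against at most 2.32 CPM in the other 3 controls, and treated replicate 1 held 19.32 CPM of SERPINA3, against at least 318.3 CPM in the other 3 treated animals. Without these 2 libraries CXCL9 gave -4.727 and SERPINA3 4.096. HMGCS1, STARD4 and SQLE then gave -1.043, -0.9906 and -0.6618, and TREM2, WIF1 and SLIT3 gave 1.334, -2.258 and -1.162. Of 14361 genes tested, edgeR called 0, with 250 at an unadjusted p under 0.05 against 718 by chance and a smallest adjusted p of 1, and the groups did not overlap in 1.62% of genes. The 250 became 855 without the 2 libraries and 679 with the replicate number as a block, with 0 called in both. DESeq2 called 6 and limma voom 0. In the simulated data for this tissue, 0 of the changed genes were recovered at a 2-fold or a 4-fold change.

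In spinal cord summed over the 3 regions of each of the 8 animals, HMGCS1 went from 323 ± 82.5 to 98.0 ± 22.2 CPM (SD, n = 4), a log2 fold change of -1.72 ± 0.26. CYP51A1 (-1.16 ± 0.17), MSMO1 (-1.23 ± 0.19), SC5D (-0.98 ± 0.14) and LSS (-0.97 ± 0.15) followed, each with an edgeR adjusted p of 0.473. Of the cholesterol genes 21 of 24 were negative (median -0.84; exact p = 0.0286), with 0 passing over all genes and 15 adjusted over the list alone. Of the fatty acid synthesis genes 12 of 15 were negative (median -0.45; exact p = 0.0286, or 0.05714 with scores from total counts), with 0 passing over all genes and 6 adjusted over the list alone. These included SCD, the stearoyl-CoA desaturase, which went from 2838 ± 698 to 1095 ± 353 CPM (-1.37 ± 0.30), FASN (-0.91 ± 0.18), FADS1 (-0.95 ± 0.19) and ACACA (-0.61 ± 0.14).

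Among cell type markers in the summed cord, microglia and macrophage genes were positive in 15 of 18 (median 0.28; exact p = 0.114), with TREM2 at 0.84 ± 0.21, CD68 at 0.60 ± 0.21 and AIF1 at 0.71 ± 0.29. Endothelial and pericyte genes were negative in 13 of 14 (median -0.54; exact p = 0.114), with RGS5 at -0.83 ± 0.19 and TEK at -0.65 ± 0.19. Of the myelin and astrocyte genes, MBP gave -0.14 ± 0.29, MOG 0.38 ± 0.18 and GFAP -0.02 ± 0.26, none past the threshold. The neuronal genes NEFH, SNAP25 and CHAT gave -1.38 ± 0.49, -0.59 ± 0.50 and -0.75 ± 0.51. CHAT turned to 0.2179 in cervical and thoracic cord alone and to 0.5248 in limma over the 24 libraries with animal as block, and GFAP to 0.2093 in the latter. The ribosomal protein genes were positive in 42 of 42 (median 0.45) without separating the groups (exact p = 0.429).

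Of 15002 genes tested in the summed cord, edgeR called 0, with 524 at an unadjusted p under 0.05 against 750.0 by chance, and the groups did not overlap in 3.16% of genes. The 524 became 1184 without the 2 lumbar libraries with almost no MOG, 950.0 in cervical and thoracic cord alone and 1372 with the replicate number as a block, with 0 called in each. DESeq2 called 57 (18 higher and 39 lower), limma voom 0, and limma voom over the 24 libraries with animal as block 24, all lower. Camera called the cholesterol list at adjusted p of 6.8e-17 in cervical, 5.5e-33 in thoracic, 5.2e-22 in lumbar and 1.1e-25 in summed cord. The thoracic call alone held with an estimated correlation (adjusted p = 0.00192), against adjusted p = 0.779, 0.128 and 0.165 with an estimated correlation in the other 3, while fry gave 0.0443, 0.000142, 0.102 and 0.0441. The fatty acid list (camera adjusted p = 3.9e-09) had adjusted p = 0.165 with an estimated correlation and 0.0670 by fry, and the microglia list (camera 0.000818) had adjusted p = 0.940 and 0.959. The microglia call was lost without control replicate 2 (median 0.16) and in cervical and thoracic cord alone (0.20). Whether the treatment effect differed between cord regions was tested in limma with animal as block: 0 of 14748 genes passed, with 107 at an unadjusted p under 0.05 (241 without 3 libraries with unusual markers) and 0 by edgeR with animal as fixed block.

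**Figure D1:**
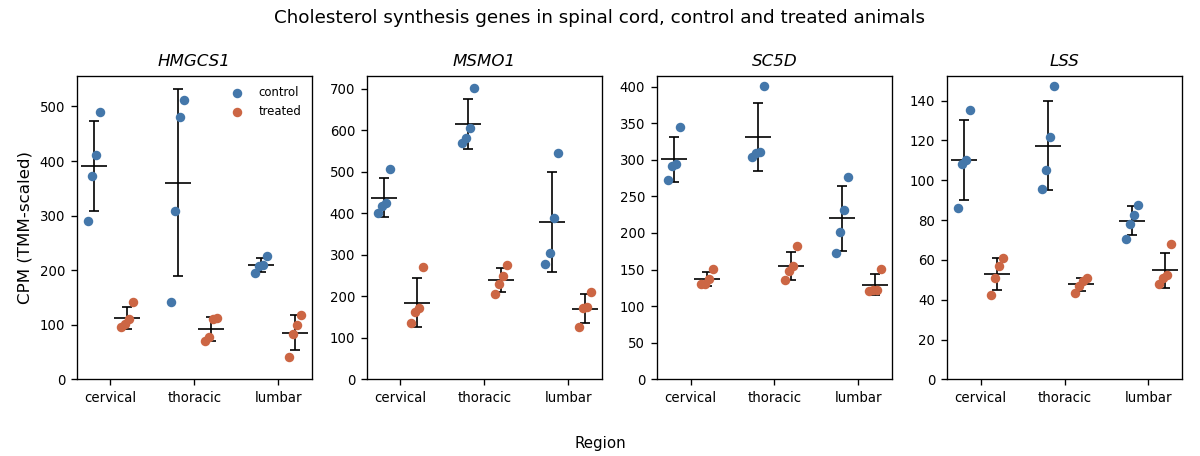
Level of 4 cholesterol synthesis genes (TMM-scaled CPM, vertical axis) in cervical, thoracic and lumbar spinal cord of control and treated animals; points are libraries and bars show the mean and SD, n = 4. In cervical cord HMGCS1 spanned 290.0 to 489.6 CPM in controls and 96.3 to 142 CPM in treated animals. The lumbar points include the 2 libraries with almost no MOG.

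In dorsal root ganglia, both regions fitted together with animal as block, genes of the neuronal cytoskeleton and of axonal transport were lower in treated animals in 26 of 26 tested members (median log2 fold change -0.71), and all 6 treated animals lay below all 4 controls in the list score (exact two-sided permutation p = 0.00476, the smallest that 4 against 6 allows). NEFH, the heavy neurofilament subunit (chromosome 10, 21996204 to 22006561), fell from 3832 ± 1535 to 759 ± 249 CPM (SD over 8 libraries per group), a log2 fold change of -2.23 ± 0.43 with a limma adjusted p of 0.0271. MAP1B, a microtubule-associated protein (chromosome 6, 70253955 to 70357894), fell by 1.16 ± 0.17 (adjusted p = 0.00703), KIF21A, a kinesin motor, by 0.96 ± 0.17 (0.0198) and DYNC1H1, the dynein heavy chain, by 0.65 ± 0.13 (0.0337) on the log2 scale in limma. Those 4 members passed over all genes and 16 passed lower when adjusted over the list alone. The markers of sensory neurons in general were negative in 10 of 13 (median -0.42), with 0 passing over all genes in limma and 3 adjusted over the list alone, and their list score differed by -0.4185 (exact p = 0.0476, or 0.1286 with scores from total counts). The other neurofilament subunits NEFL and NEFM gave -1.09 ± 0.27 and -1.01 ± 0.31, with limma adjusted p of 0.0684 and 0.159.

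The smallest p in ganglia belonged to CCNI, a cyclin gene abundant in neurons (chromosome 5, 57424237 to 57453477), which fell from 288 ± 29.1 to 113 ± 12.2 CPM (log2 fold change -1.34 ± 0.14, limma adjusted p = 0.000596). TIMP2, an inhibitor of metalloproteinases, fell by 1.34 ± 0.18, and CADM3, a neuronal adhesion molecule, by 1.32 ± 0.17 on the log2 scale. RNF157, PCNX2, DNM1, CYB5R3, ACKR1 and RTL9 also fell, by 1.22 to 1.44 on that scale. Heat shock protein genes fell in 2 of 12 members, HSP90AA1 by 0.99 ± 0.14 and its co-chaperone gene DNAJA1 by 0.55 ± 0.12. The 2 genes that rose were ARHGAP24 (0.52 ± 0.11) and PANK4 (0.52 ± 0.12), and neither passed on counts summed per animal or with the replicate number as a block. No member of the nerve injury list passed over all genes, and 2 of 24 passed lower when adjusted over the list alone. ATF3, GAP43 and GAL, which the rule names whatever their p, gave -0.55 ± 0.46, -0.18 ± 0.24 and 0.04 ± 0.54. Nociceptor markers were negative in 15 of 20 (median -0.31), with SCN10A at -0.75 ± 0.31, P2RX3 at -0.90 ± 0.32, SCN9A at -0.63 ± 0.22 and CALCA at -0.31 ± 0.37, none past the threshold. The Schwann cell gene PMP22 gave 0.03 ± 0.21, and the macrophage gene AIF1 gave 0.43 ± 0.28.

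Of 14535 genes tested in ganglia, limma with animal as block called 137, 2 higher and 135 lower, 32 of them by at least 1 on the log2 scale. Over all 16 libraries, the groups did not overlap in 1.53% of genes. The share expected by chance for 4 against 4 does not apply to this value, since groups of more libraries overlap more readily by chance. The animal correlation was 0.718. The count fell to 3 without P0004, 3 without P0501, 4 without P0003, 36 without P0402, 67 without P0403 and 70 without P0406, and was 963 without P0905. It was 13 on counts summed per animal in edgeR and 46 with the replicate number as a block, all lower, and 962 in edgeR with no animal block (237 higher). Camera called the cytoskeleton list at an adjusted p of 9.1e-19, with an adjusted p = 0.0809 with an estimated correlation and 0.0382 by fry.

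**Figure D2:**
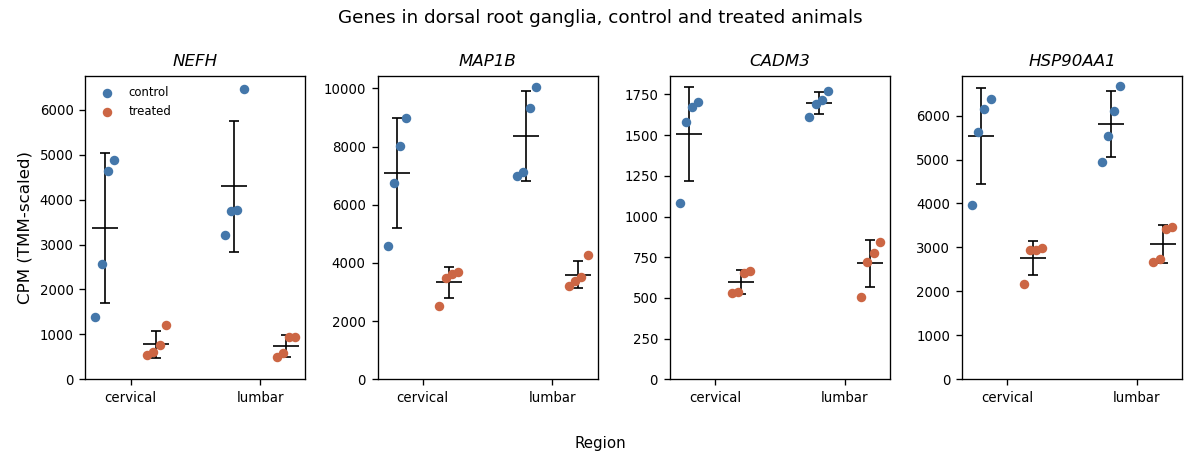
Level of NEFH, MAP1B, CADM3 and HSP90AA1 (TMM-scaled CPM, vertical axis) in cervical and lumbar dorsal root ganglia of control and treated animals; points are libraries and bars show the mean and SD, n = 4. In lumbar ganglia NEFH spanned 3215 to 6451 CPM in controls and 489 to 950.4 CPM in treated animals.

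In lumbar ganglia alone, 8 of the 26 cytoskeleton genes fell, and all 26 were negative (median -0.63; exact p = 0.0286), with 17 passing lower when adjusted over the list alone. NEFH fell from 4353 ± 1479 to 749.8 ± 243 CPM (SD, n = 4), a log2 fold change of -2.58 ± 0.32 with an edgeR adjusted p of 0.0154. NEFL fell by 1.35 ± 0.19 and NEFM by 1.11 ± 0.24, TUBA4A, a tubulin, by 1.32 ± 0.19 and KIF21A by 0.93 ± 0.14 on the log2 scale. Of the voltage-gated channel genes 4 of 28 fell, including HCN2, a pacemaker channel (-1.47 ± 0.17), and 25 were negative (median -0.31), with 7 passing lower and 1 higher when adjusted over the list alone. Of the markers of large-diameter sensory neurons, such as proprioceptors, 3 of 19 fell, including NEFH and ASIC1, an acid-sensing channel (-0.47 ± 0.09), and 18 were negative (median -0.46), with 5 passing lower when adjusted over the list alone. The presynaptic gene SNAP25 fell by 1.21 ± 0.15, SYN1 by 1.45 ± 0.27 and the neuronal ubiquitin hydrolase UCHL1 by 0.92 ± 0.19. Heat shock genes fell in 2 of 12 members (HSP90AA1, -0.91 ± 0.16, and the co-chaperone BAG3, -0.95 ± 0.17), and fatty acid synthesis genes in 2 of 15 (ACLY, -0.75 ± 0.14, and FASN, -1.05 ± 0.20). Nociceptor markers passed in 0 of 20 members in edgeR (median -0.20).

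The other lumbar genes named by the rule included HSPB6, a small heat shock protein (chromosome 19, 36205055 to 36207530), which fell from 262 ± 54.3 to 53.6 ± 17.96 CPM (SD, n = 4), and CDR2L (chromosome 16, 72233471 to 72251605), which had the smallest edgeR adjusted p (0.00826) and fell by 1.73 ± 0.15 on the log2 scale. CABP7, a calcium-binding protein, fell by 2.67 ± 0.40, the platelet chemokine gene PF4V1 by 2.20 ± 0.36, CAMK2N2 by 2.00 ± 0.26, CXCL6 by 1.98 ± 0.41, HAPLN4, a link protein of perineuronal matrix, by 1.69 ± 0.29, CHRNA4, a nicotinic receptor subunit, by 1.66 ± 0.23, and KCNN1 by 1.66 ± 0.34. Of the 91 genes that rose, CD5L, a product of tissue macrophages (chromosome 1, 93882650 to 93893368), went from 2.68 ± 2.08 to 26.2 ± 16.5 CPM (log2 fold change 3.48 ± 0.51). CACNG5 (2.41 ± 0.42), TREH (1.59 ± 0.35), PLCH1 (1.19 ± 0.25) and FSIP2 (1.16 ± 0.21) followed, and FILIP1L, LRIG3, HAS3, ZNF888 and GULP1 rose by 0.75 to 0.97. Ribosomal protein genes were positive in 41 of 42 (median 0.32; exact p = 0.0286), with 0 passing in edgeR over all genes or adjusted over the list alone. The genes of non-canonical poly(A) polymerases and RNA 3-prime end decay were positive in 27 of 29 (median 0.22; exact p = 0.0286), with 0 passing over all genes and 3 adjusted over the list alone (PAN3, 0.42 ± 0.10, and TUT4, 0.55 ± 0.14, had the smallest p of the list). Interferon-stimulated genes were positive in 27 of 27 (median 0.95; exact p = 0.486), and treated replicate 1, from P0406, held 1257 CPM of MX1 against at most 577 CPM in the other 7 libraries.

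Of 14267 genes tested in lumbar ganglia, edgeR called 612, 91 higher and 521 lower, 110 of them by at least 1 on the log2 scale, and the groups did not overlap in 2387 genes (16.7%, against 2.86% by chance). DESeq2 called 1728 (535 higher and 1193 lower), limma voom 593 (76 higher) and the fit of all 48 libraries 64 (2 higher). The count was 32, 70, 18 and 303 without control replicates 1, 2, 3 and 4, of which 0, 2, 0 and 21 were higher. It was 670 (102 higher), 467 (54 higher), 173 (7 higher) and 200 (9 higher) without treated replicates 1, 2, 3 and 4. Camera called the cytoskeleton (adjusted p = 8.4e-13), large-diameter (2.9e-05) and voltage-gated channel (0.000142) lists. Each had an adjusted p = 0.915 with an estimated correlation, and 0.0873, 0.108 and 0.108 by fry.

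In cervical ganglia, 25 of 26 cytoskeleton genes were negative (median -0.59; exact p = 0.0571), with 0 passing over all genes and 11 adjusted over the list alone. CCNI went from 301 ± 34.5 to 111 ± 13.4 CPM (SD, n = 4), a log2 fold change of -1.45 ± 0.15 with an edgeR adjusted p of 0.109. CADM3 (-1.35 ± 0.18), NEFH (-2.04 ± 0.28), MXRA7 (-1.06 ± 0.15) and TNFRSF21, a death receptor of neurons (-1.10 ± 0.16), had an edgeR adjusted p of 0.249, as did P2RX3, an ATP-gated channel of nociceptors (174.6 ± 51.59 CPM in controls and 88.69 ± 34.63 CPM in treated animals). The share of mitochondrial transcripts was 23.01% in treated replicate 4, from P0905, against 6.97% to 13.4% in the other 7 libraries. Of 14173 genes tested, edgeR called 0, with 1042 at an unadjusted p under 0.05 against 709 by chance, and 2 without treated replicate 4. The groups did not overlap in 5.48% of genes. DESeq2 called 223 (20 higher and 203 lower), limma voom 0 and the fit of all 48 libraries 60. The cytoskeleton call of camera (adjusted p = 1.4e-14) had an adjusted p = 0.780 with an estimated correlation and 0.162 by fry. The difference of the treatment effect between the 2 ganglion regions, tested in limma with animal as block, passed for 0 of 14535 genes, with 416 at an unadjusted p under 0.05, and 113 of the 612 genes called in lumbar ganglia were among the 137 called over both regions.

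No gene passed in 2 or more of the 6 tissues in the same direction, since lumbar ganglia alone had calls. Across 12438 genes, the log2 fold changes in liver and in summed cord of the same 8 animals had a Pearson r of 0.0844, a Spearman rho of 0.0390 and a covariance of 0.00973. Other splits of the 8 animals gave a median r of 0.104 and a median covariance of 0.0108, and 22 of the 35 splits had an r as large as the real split. Genes are not independent replicates, so these values carry no p.

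The cord regions differed in HOX genes, which mark position along the body axis. These comparisons include the 2 lumbar libraries with almost no MOG. Lumbar against cervical cord of the same animals gave 8 genes in edgeR with animal as block, 5 higher and 3 lower. HOXD10 stood at 0.0117 ± 0.0219 CPM (SD, n = 8) in cervical and 25.7 ± 21.9 CPM in lumbar cord (adjusted p = 7.5e-05), HOXA11 at 0.0133 ± 0.0197 and 9.36 ± 5.51 CPM, HOXA10 at 0.255 ± 0.193 and 28.6 ± 10.1 CPM, and HOXA9 at 3.36 ± 2.34 and 33.4 ± 6.11 CPM. MYOC rose by 2.68 ± 0.44 on the log2 scale, while RFX2, EHHADH and IQCK were lower by -0.91 ± 0.14, -0.64 ± 0.11 and -0.57 ± 0.10. The count was 0 in control animals alone and 0 in treated animals alone in edgeR, with 1379 and 764 at an unadjusted p under 0.05, and 17 with a minimum mean of 1 CPM.

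Thoracic cord differed from the other regions in many genes, 5799 against cervical (3302 higher) and 7277 for lumbar against thoracic (3470 higher) of 14419 tested in edgeR. Liver and plasma protein genes were among the largest: ALB stood at 52.6 ± 68.5 CPM (SD, n = 8) in thoracic and 1.013 ± 1.395 CPM in lumbar cord, with FGA, FGG and APOA2 in the same direction. By total counts, ALB reached 97.38 CPM in thoracic control replicate 4 and 125.89 CPM in treated replicate 4, the 2 thoracic libraries with the highest mitochondrial share (37.26% and 36.43%), against 0.97 to 33.64 CPM in the other 6. CARTPT, a neuropeptide, went from 40.3 ± 21.4 to 3.31 ± 3.69 CPM. SLC36A2, PLEKHG7 and FGF4 were higher in lumbar than thoracic cord, and the SDs of their lumbar means (83.5, 90.4 and 10.2 CPM) exceeded the means (57.3, 63.2 and 5.49 CPM). The thoracic against cervical count was 1743 in control animals alone and 0 in treated animals alone in edgeR, with 3824 at an unadjusted p under 0.05. The lumbar against thoracic count was 3160 and 1433, and the mitochondrial share of thoracic libraries ran from 10.5% to 37.3%.

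Lumbar against cervical ganglia gave 29 genes in limma with animal as block, 12 higher and 17 lower of 14168 tested. HOXC10 stood at 0.00515 ± 0.0146 CPM (SD, n = 8) in cervical and 7.81 ± 3.10 CPM in lumbar ganglia (adjusted p = 5.7e-08), HOXC9 at 0.0573 ± 0.0448 and 5.92 ± 1.22 CPM, HOXA10 at 0.0703 ± 0.0870 and 22.9 ± 5.00 CPM, and HOXA9 at 0.716 ± 0.724 and 44.6 ± 6.44 CPM. HOXC8, HOXB9, HOXD9 and HOXC6 rose by 4.46 ± 0.60, 2.21 ± 0.42, 1.61 ± 0.19 and 1.53 ± 0.30, and HOXB4 and HOXC5 gave -0.65 ± 0.09 and -0.65 ± 0.11. SLC22A3, a cation transporter, ANGPTL7 and CYP21A2 fell by 1.86 ± 0.28, 1.60 ± 0.30 and 1.52 ± 0.28 on the log2 scale. The count was 6 in control animals alone, 7 in treated animals alone and 13 in edgeR with animal as fixed block.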

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

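Every test in this part, including the splits of animals, was chosen or given its bounds after the result was seen.

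Lower cholesterol synthesis genes in treated spinal cord were set apart because the effect differed between tissues of the same animals. The treated minus control difference of the list score in summed cord lay below that in liver by a difference of -0.7206 and below that in ganglia by -0.7817, each with an exact permutation p of 0.0286 over 4 and 4 animals, with 4 of 4 treated animals below all controls. A loss of oligodendrocytes and astrocytes was tested with the cholesterol minus glial score, which still differed by -0.6649 (exact p = 0.0286), while the glial score alone differed by -0.05. The 2 lumbar libraries without cord markers could also have driven it, but the median without them was -0.8276. Both values speak against these 2 technical explanations. They leave a response of cord cells to treatment possible, which no test here separates from other cell changes. In the 2 libraries themselves, HMGCS1 had 209.3 CPM in control replicate 1 and 41.34 CPM in treated replicate 1, and LSS had 87.38 and 67.8 CPM. Lower levels were thus also seen where cord markers were almost absent, but from 1 library per dose group, which cannot decide where the change arose.

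Lower neuronal cytoskeleton genes in treated ganglia could come from fewer neurons per library. The pan-sensory neuron score itself differed by -0.4185 (exact permutation p = 0.0476 over 4 and 6 animals, or 0.1286 with scores from total counts), against -0.7661 for the cytoskeleton score. The cytoskeleton minus pan-sensory neuron score differed by -0.402 (exact p = 0.081), so this explanation can be neither dropped nor kept. Leaving out P0905 and P0406, whose ganglion libraries had a high mitochondrial share and high interferon genes in turn, left a median of -0.5569, which speaks against those 2 animals as the source. A treatment effect on neurons remains possible beside a change in the share of neurons.

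In lumbar cord, control replicate 1 and treated replicate 1 had at most 0.258 CPM of MOG and 65.6 CPM of GFAP, against at least 330.0 and 7125 CPM in the other 22 cord libraries. A swap with a ganglion library did not match, since the highest MOG level among the 16 ganglion libraries was 2.144 CPM. Ganglion tissue in place of cord did not match either, since SCN10A reached 0.2174 CPM at most, against at least 85.6 CPM in ganglia. No biological explanation was tested, as 1 library of each dose group was affected.

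In Dixon's test, which by chance marks about 1 in 20 groups, 2 of 36 library measures, 1 of 26 list scores and 9 of 206 gene levels had 1 sample far from the other 3. In liver, control replicate 2 had a mitochondrial share of 11.83% and a mitochondrial list score of 12.93, control replicate 3 had 77.35 CPM of CYP7A1, and treated replicate 2 had 9370.0 CPM of CYP3A4. In lumbar cord, control replicate 1 had 19.26 CPM of CXCL9 and treated replicate 1 had 19.32 CPM of SERPINA3. In lumbar ganglia, treated replicate 1 had 12.8 CPM of PLCH1 and its most abundant gene held 2.133% of counts, control replicate 1 had 6538 CPM of NEFH, and control replicate 2 had 27.86 CPM of HCN2. In summed cord, treated replicate 4 had 57.82 CPM of CYP51A1 and control replicate 1 had 108.6 CPM of ACACA.

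When the treatment labels were moved to other splits of the animals, the real split counted among those as large. The median of the cholesterol list was as far from 0 in 1 of 35 splits in cervical (highest other 0.742), thoracic (0.7097), lumbar (0.6341) and summed cord (0.6857). For the fatty acid list in summed cord it was 2 of 35 (0.4781) and for the microglia list 12 of 35 (0.5736). In liver it was 2 of 35 for the unfolded protein response (0.4424) and the mitochondrial genome (0.5808), and 7 of 35 for AHR targets (1.269). For the cytoskeleton list it was 3 of 35 in cervical ganglia (0.6677), 2 of 35 in lumbar ganglia (0.6337) and 3 of 100 in ganglia together (0.8774). For the large-diameter list in lumbar ganglia it was 3 of 35 (0.542), and for voltage-gated channels 5 of 35 (0.3703).

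For genes past the threshold, 1 of 35 splits was as large in lumbar ganglia (612, highest other 2). In ganglia together it was 3 of 100 (142 with a correlation taken from fewer genes, highest other 668). For region comparisons, region labels were reassigned instead of treatment labels. They were swapped within animals in cord, and dealt to ganglion libraries at random without keeping the libraries of an animal paired. As many genes came from 1, 1, 1 and 2 of 100 such assignments for thoracic against cervical (highest other 4049), lumbar against thoracic (6030.0), lumbar against cervical cord (0) and lumbar against cervical ganglia (36). For genes at an unadjusted p under 0.05, as many came from 2 of 35 splits in liver (highest other 1107, the split by sex), 5 in cervical cord (2842), 17 in thoracic cord (5380.0), 14 in lumbar cord (3154, the split by sex), 14 in summed cord (4015) and 6 in cervical ganglia (3685). The split by sex was fitted without the sex term that the other splits have, so its counts are not comparable with theirs. Over the other 34 splits, as many came from 1 in liver (highest other 901), 5 in cervical cord (2842), 16 in thoracic cord (5380.0), 13 in lumbar cord (2719), 13 in summed cord (4015) and 6 in cervical ganglia (3685). The thoracic split of 5380.0 genes parted the 4 libraries with the highest mitochondrial shares from the rest. Among the 8 splits of a tissue that part all 4 replicate numbers, the real split gave the most genes in liver (1049; next 530.0), cervical cord (1356; 945), lumbar cord (250.0; 221) and lumbar ganglia (3225; 763). It came after 1 other split in thoracic cord (327; 735), summed cord (524; 652) and cervical ganglia (1042; 2181). As many genes came from 31 of 35 splits for the cord interaction (5058, the split by sex; 30 of 34 and 4236 without it) and 83 of 100 for the ganglion interaction (2629), and 22 of 35 had a covariance between liver and cord as large (0.03077). Camera called as many lists in 11 of 35 splits in liver, 28, 26, 27 and 29 of 35 in cervical, thoracic, lumbar and summed cord, 24 and 17 of 35 in cervical and lumbar ganglia, and 55 of 100 in ganglia together, so its preset p values overstate the evidence for a list here.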

How the results depend on the processing

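The settings that leave out libraries by their markers, by mitochondrial share or by animal pair, the left-out replicates of lists and the other scalings of list scores were chosen after the data were seen. Among named genes, 979 of the planned values kept their direction and side of the threshold, 123 no longer passed, 68 newly passed and 5 reversed; with 1 replicate left out these were 845, 233, 3 and 23. Of the counts of calls, 60 stayed within 1.5 times and 30 moved under planned settings. Medians of lists were not tallied under the planned settings. They kept their direction with 1 replicate left out (112 on the same side of the camera threshold as in the main fit, 2 no longer past it) and in the settings added later (22 and 1). The range over left-out replicates was -0.499 to -0.335 for the unfolded protein response, -0.958 to -0.727 for cholesterol genes in summed cord and -0.836 to -0.637 for cytoskeleton genes in ganglia. In the simulated data, at most 22% of 2-fold changes between treated and control cord were recovered with 4 animals per group. With the same group size, 57% were recovered in liver and 49% in lumbar ganglia. The cause of the changes below was not tested.

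DESeq2 called 193 genes in liver, 108, 28 and 6 in cervical, thoracic and lumbar cord, 57 in summed cord, 223 in cervical and 1728 in lumbar ganglia, and 27 for sex in liver. A fit of all 48 libraries called 23 in liver, 11 and 18 in cervical and thoracic cord, and 60 and 64 in cervical and lumbar ganglia. Without a filter, edgeR called 2 in cervical cord, and limma voom with animal as block called 24 in summed cord. With the replicate number as a block (paired fit), lumbar ganglia had 206 calls (9 higher) and ganglia together 46, all lower, and it changed no other count of calls from 0. At an unadjusted p under 0.05 it gave 790.0 genes against 327 in thoracic, 679 against 250 in lumbar and 1372 against 524 in summed cord. Without the 2 lumbar libraries that lacked cord markers these were 855 in lumbar and 1184 in summed cord, with 950.0 in cervical and thoracic cord alone. Same-number correlations over 0.1 numbered 3 of 4 in liver, cervical and thoracic cord and 0 in both ganglia. In ganglia together, edgeR called 13 on summed counts, all lower, 962 without the animal block, and limma 891 without P0905 and P0406. Leaving out 1 replicate gave 18 to 670.0 calls in lumbar ganglia, 0 to 2 in cervical ganglia and 3 to 963 by animal in ganglia together.

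Thoracic against cervical cord gave 1743 calls in controls and 0 in treated animals alone, lumbar against thoracic 3160.0 and 1433, and lumbar against cervical 0 and 0, 5 with no animal block and 17 at 1 CPM or more. Without 3 cord libraries with unusual markers (lumbar control replicate 1 and treated replicate 1, cervical control replicate 1) the counts were 6941 (5550.0 shared with the 5799), 7346 (5926 of the 7277) and 12 (6 of the 8). Ganglion regions gave 13 in edgeR, 6 in controls and 7 in treated animals. Over all fits, camera called 89 lists, 1 with an estimated correlation and 5 by fry.

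Adjusted p with an estimated correlation, then by fry, were 0.489 and 0.245 for the unfolded protein response, 0.489 and 0.267 for AHR targets, and 0.694 and 0.366 for the mitochondrial genome in liver. In cord the estimated correlation gave 0.779 (cervical) and 0.165 (summed) for cholesterol, and fry, which asks another question, gave 0.0443 and 0.0441. Lumbar cholesterol had 0.128 and 0.102, summed fatty acid genes 0.165 and 0.0670, and microglia 0.940 and 0.959. Cytoskeleton genes had 0.780 and 0.162 in cervical, 0.915 and 0.0873 in lumbar and 0.0809 and 0.0382 in joint ganglia. Large-diameter markers and voltage-gated channels in lumbar ganglia each had 0.915 and 0.108. The AHR median ran from 0.45 to 1.34 and the microglia median from 0.15 to 0.55 with 1 replicate left out, and the latter was 0.16 without control replicate 2 and 0.20 in cervical and thoracic cord, past no threshold. The median of the mitochondrial genome ran from -0.627 to -0.2584 with 1 replicate left out, the latter without control replicate 2, and moved nearly as far without treated replicate 2. With list scores from total counts in place of TMM, exact p rose past 0.05 for the unfolded protein response in liver (0.1143), endothelial and pericyte genes in cervical cord (0.05714), fatty acid genes in summed cord (0.05714), and general sensory neuron (0.1286) and large-diameter markers (0.1429) in ganglia. The other 43 exact p values under the 2 other scalings stayed on the same side of 0.05.

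Genes near 0 changed sign. In liver, TENT4A ran from -0.0677 to 0.136, TENT4B from -0.187 to 0.0159, ZCCHC14 from -0.0397 to 0.0755 and CYP7A1 from -0.51 to 0.27 with 1 replicate left out, and ZCCHC14 was -0.0011 in the fit of all libraries. In summed cord, MBP ran from -0.35 to 0.00995 and GFAP from -0.18 to 0.13. GFAP was 0.0123 without sex and 0.21 in limma with animal as block, where CHAT was 0.52, and CHAT was 0.22 in cervical and thoracic cord, but -0.7213 without the 2 lumbar libraries that lacked cord markers. In ganglia GAL ran from -0.15 to 0.32 and PMP22 from -0.10 to 0.13, with PMP22 at -0.00216 without the animal block and -0.20 without P0905 and P0406.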

Other observations

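The lysosomal list and the comparison of neuron types below were chosen after the data were seen.

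In treated liver, genes of lysosomal proteins were lower in 45 of 50 tested members (median log2 fold change -0.20), with 0 passing in edgeR over all genes and 17 adjusted over the list alone. FUCA1, which codes for a lysosomal fucosidase, gave -0.83 with an edgeR adjusted p of 0.231, beside GNPTG (-0.78 ± 0.10), which serves the tagging of lysosomal enzymes. Camera gave an adjusted p of 2.0e-15, with adjusted p = 0.0647 with an estimated correlation and 0.0258 by fry. List p values in this paragraph were adjusted only over this list and the same list without the members seen first. They are therefore not comparable with those of the lists written beforehand, which were adjusted over all lists of a fit. The hypothesis that lysosomal genes are lower as a group was tested on the 42 members not seen first. Of these 37 were negative (median -0.17), and the score had an exact two-sided permutation p of 0.05714 over 4 and 4 animals, with 3 of 4 treated animals below all controls (exact p = 0.8571 with scores from total counts), so the test does not decide. In lumbar ganglia 8 of the 50 genes fell in edgeR (11 adjusted over the list alone), and in summed cord 32 of 50 were positive (camera adjusted p = 0.691).

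A larger fall of large-diameter sensory neuron markers than of nociceptor markers in ganglia was also tested. The large-diameter score differed by -0.381 (exact permutation p = 0.0143 over 4 and 6 animals, or 0.1429 with scores from total counts) and the nociceptor score by -0.339 (exact p = 0.271). Their difference was -0.0425 over both regions (exact p = 0.8476) and -0.394 in lumbar ganglia alone (exact p = 0.4 over 4 and 4 animals), so neither test decides.

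Libraries of the same animal were compared across tissues by their deviation from tissue means. The best match was a library of the same animal in 11 of 12 comparisons within ganglia, 17 of 26 between ganglia and liver, 26 of 48 between liver and cord, 45 of 78 between ganglia and cord, and 19 of 48 within cord, against 1.5, 3.25, 6, 9.75 and 6 expected if every library were an equally likely match. Libraries of the same animal also share dose group and sex, which deviations from tissue means keep. The matches therefore cannot be credited to the animal alone. Libraries of P0905 had mitochondrial shares of 25.7%, 36.4% and 27.04% in cervical, thoracic and lumbar cord.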
